A study of Mus musculus with 16 samples.

How the data were processed

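The samples were mouse CD4 T cells from Ezh2-floxed mice with a Cd4-driven Cre (Ezh2-deleted) and from floxed mice without Cre (control). Naive cells were sorted by flow cytometry and stimulated with 5 ug/ml anti-CD3 and 1 ug/ml anti-CD28. Th0 cultures had 50 U of IL-2, and iTreg cultures had 200 U/ml of IL-2 and 5 ng/ml of TGF-beta1. The sample titles give day 5 for iTreg and day 4 for Th0, while the protocol gives harvest on day 4. RNA was sequenced from 3 libraries in each of the 4 combinations of genotype and culture. H3K27me3 ChIP-seq, with 10 ug of antibody per ChIP, came from 2 libraries per genotype in Th0 cells, and no input or spike-in library was used here.

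Per the labels, the authors trimmed reads with Trimmomatic 0.30, aligned RNA reads with TopHat2 2.0.6 and ChIP reads with Bowtie2 2.1.0 to mm10, and counted them with featureCounts 1.4.2. The deposited RNA values are raw read counts per gene. The deposited ChIP values are raw read counts per gene interval, the whole gene body. All 1254 intervals wholly covered by others held no reads, against 9 of 17394 without overlap, which is what counting leaves when reads in more than 1 interval are dropped; the labels read here do not state that step. Every value was a whole number, which was checked on the files. The RNA files held 23420 genes, 5740 of them without a read in any library. The ChIP files held 22269 intervals, 4875 (21.9%) overlapping another and 1293 without a read, and 22265 names were shared by both kinds of file.

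Library totals set the depth. The Th0 control libraries 173, 176 and 177 had 24589438, 26973319 and 26184692 counted reads, and the Th0 Ezh2-deleted libraries Ezh2KO.165, Ezh2KO.174 and Ezh2KO.175 had 25889519, 26922332 and 28443427. The iTreg control libraries 154, 155 and 177 had 26259941, 24515454 and 24817500, and the iTreg Ezh2-deleted libraries Ezh2KO.150, Ezh2KO.153 and Ezh2KO.165 had 24213721, 23322080 and 21910114. ChIP totals were 11124172 and 12433039 (control 33 and 7) and 15103496 and 11133166 (Ezh2KO.10 and Ezh2KO.9). Libraries go by the numbers in their titles, with Ezh2KO before those of Ezh2-deleted libraries. Counts are reads without molecular identifiers, so a floor of 3 counts for a value of 0 covers counting error only. A gene with no reads in a group is given by its CPM without a fold change.

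RNA was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr with a minimum count of 10 (12845 genes tested), and a robust quasi-likelihood F test with all 12 libraries in 1 fit of 4 groups. The common dispersion was 0.0810. Contrasts were Ezh2-deleted against control in Th0 and in iTreg, their average, their difference (the interaction), and iTreg against Th0 within each genotype. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. ChIP counts were tested the same way with 2 libraries per genotype (20376 intervals tested), scaled by library size alone, because loss of the enzyme can lower the mark broadly and TMM assumes that most intervals do not change. H3K27me3 density is CPM per kb of the gene interval. Marked genes were the 10% with the highest mean density in control cells among 12592 genes tested in RNA and present in the ChIP files. Their RNA change was tested with camera (limma 3.58.1, preset correlation 0.01, and with an estimated correlation), with Fisher's exact test and against 10000 random lists matched on mean expression.

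Gene lists numbered 28 with 436 symbols, of which 434 were found, 4 under an older symbol. They covered PRC2, PRC1, Cdk inhibitors, p53 targets, proliferation, apoptosis, glycolysis, interferon response, Th1, Th2, Th17, Treg, Tfh, TGF-beta response, cytotoxic, inhibitory receptor, naive and memory, T cell identity, Hox, developmental transcription factor, housekeeping and sex-linked genes, and markers of B, myeloid, dendritic, CD8 T, NK with NKT and gamma-delta T, and erythroid cells. Lists with at least 3 tested members were tested with camera, adjusted over the lists of a contrast. Genes were named by a rule: Ezh2, 14 fixed genes, and per contrast the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap of CPM between groups (10% of genes would not overlap by chance with 3 against 3). Predicted genes, Xist, Y-linked genes and antigen receptor segments were left out. Up to 4 members per list with the smallest p, the 5 smallest interaction p, and for H3K27me3 the 5 largest losses and 5 largest gains with at least 20 counts per library in the higher group were added. The groups, tests, lists, naming rule and most alternatives were set before the data were examined.

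The tests were also tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In Th0, 44% and 80% were recovered with 2 false calls of 126, and in iTreg 35% and 79% with 5 of 119. For H3K27me3 43% and 99% were recovered, with 32 false calls of 174. That false share lies above the threshold set for the adjusted p, unlike those of the RNA tests. H3K27me3 calls close to the threshold are therefore less certain than their adjusted p states. Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter, a strict filter of 5 CPM in 3 libraries, the 2 groups alone, the animal number as a random effect (limma voom), sex as a covariate, each library left out in turn, and for ChIP TMM scaling, scaling on highly expressed genes (those with the most control Th0 RNA), and other definitions of marked genes. Chosen after seeing the data were a term for the iTreg libraries Ezh2KO.165 and 177 against the other iTreg libraries, leaving these 2 out, leaving out Ezh2KO.165 in both cultures, leaving out overlapping intervals, and measuring the mark of genes chosen in 1 control ChIP library against the other. The numbers of Ezh2KO.165 and 177 occur in both cultures, but no paired analysis was possible because the groups compared share fewer than 2 numbers. Overlaps of intervals were found with GenomicRanges 1.54.1. Raw reads, peaks, splice forms and H3K27me3 in iTreg were not analysed here.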

Results

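The data hold gene expression and a repressive histone mark in mouse CD4 T cells with and without Ezh2, the enzyme of Polycomb repressive complex 2 that trimethylates histone H3 at lysine 27 (H3K27me3). Mice with floxed Ezh2 and a Cre recombinase driven by Cd4 gave the Ezh2-deleted cells, and floxed mice without Cre gave the controls. Naive CD4 T cells isolated by flow sorting were stimulated through CD3 and CD28 in 2 ways. Th0 cultures had IL-2 alone, and iTreg cultures had more IL-2 and TGF-beta1, a cytokine that induces Foxp3 and the regulatory T cell state. RNA was sequenced from 3 biological replicates per genotype and culture (12 libraries, 21910114 to 28443427 counted reads each). H3K27me3 ChIP-seq came from 2 replicates per genotype in Th0 cells (4 libraries, 11124172 to 15103496 counted reads). The series asks which genes depend on Ezh2 and how these relate to the mark, so each genotype comparison is followed by its relation to H3K27me3.

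Genotype and culture both separated the RNA libraries. The first principal component held 46.5% of the variance and the second, which parted the genotypes, 25.9%. Th0 libraries lay between 39.7 and 57.7 on the first component, and the iTreg libraries Ezh2KO.150, Ezh2KO.153, 154 and 155 between -44.9 and 1.87. The iTreg libraries Ezh2KO.165 (Ezh2-deleted) and 177 (control) lay farther out, at -109 and -98.2. Replicate spread in iTreg was wide for this reason: Ezh2KO.165 differed from Ezh2KO.150 and Ezh2KO.153 with a chi-square per degree of freedom of 442 and 471, against 5.26 between Ezh2KO.150 and Ezh2KO.153. The Th0 libraries of the same 2 numbers did not stand apart in this way.

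Th0 cells without Ezh2 had more transcripts of cytotoxic and T helper 1 genes and of the cell cycle inhibitors at the Cdkn2 locus, and fewer of Ctla4 and Foxp3. Ezh2 (chromosome 6, 47530274 to 47595341 in mm10) itself had 158 ± 10.6 CPM (read counts scaled to the library total, mean ± SD, n = 3) in Ezh2-deleted and 314 ± 6.79 CPM in control Th0 cells. This log2 change of -0.99 did not pass the threshold with all 12 libraries in 1 fit (edgeR adjusted p = 0.0618). Its adjusted p was 0.000670 without iTreg Ezh2KO.165 and 7.67e-08 with the 6 Th0 libraries alone. Ezh2 was lower in every Ezh2-deleted library than in every control library of its culture. Gzma, a granule protease of killer cells (chromosome 13, 113093825 to 113100979), rose from 1.18 ± 0.252 to 320.0 ± 68.3 CPM (log2 change 8.07, SE 0.957, adjusted p = 0.000664). Eomes, a transcription factor of cytotoxic and memory T cells (chromosome 9, 118478212 to 118486132), rose from 29.5 ± 4.39 to 620.3 ± 93.6 CPM (log2 change 4.39, SE 0.613, adjusted p = 0.00163). Interferon gamma (Ifng, chromosome 10, 118441047 to 118445892) rose from 0.525 ± 0.297 to 21.3 ± 8.52 CPM (log2 change 5.32, adjusted p = 0.00389). Tbx21, the T helper 1 master factor, had 28.7 ± 2.58 and 35.9 ± 3.48 CPM (log2 change 0.32, adjusted p = 0.624). Il10 (0.0539 to 12.6 ± 14.5 CPM), the chemokine receptor Ccr2 (2.31 to 177 ± 47.5 CPM), Igj, Cyp1b1, Gcnt2, Esm1 and Xcl1 completed the 8 largest rises, with log2 changes of 5.98 to 7.76 and adjusted p of 0.000144 to 0.00834. Igj varied between the Ezh2-deleted Th0 libraries as B cell markers did, at 53.1, 19.9 and 15.8 CPM in Ezh2KO.165, Ezh2KO.174 and Ezh2KO.175 (log2 ratio of Ezh2KO.165 to the other 2 of 1.57, against a median of 1.07 for the B cell list).

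Inhibitors of the cell cycle and further T cell regulators changed as well. Cdkn2a, the Polycomb target that encodes p16 and p19 (chromosome 4, 89274471 to 89294653), rose from 1.25 ± 0.167 to 46.3 ± 10.0 CPM (log2 change 5.20, SE 0.975, adjusted p = 0.00749). Its neighbour Cdkn2b rose by 5.82 (adjusted p = 0.00297). Bmi1, a Polycomb complex 1 subunit that represses Cdkn2a (chromosome 2, 18677018 to 18686629), rose from 74.9 ± 3.54 to 229.9 ± 10.9 CPM (log2 change 1.62, adjusted p = 4.99e-05). Ctla4, an inhibitory receptor (chromosome 1, 60887000 to 60915832), fell from 305 ± 41.4 to 14.7 ± 1.95 CPM (log2 change -4.37, SE 0.421, adjusted p = 0.000248). The regulatory T cell factor Foxp3 (chromosome X, 7579676 to 7595243) fell from 21.5 ± 4.53 to 3.94 ± 2.01 CPM (log2 change -2.45, adjusted p = 0.00113). Abi3bp, Dapl1, Nrn1, Cdhr3, Igfbp7, Stxbp6 and Trat1 were the other large falls, with log2 changes of -5.15 to -3.37 and adjusted p of 8.69e-05 to 0.00452. The type 2 cytokine Il13 rose by 3.53 (adjusted p = 0.0196, with adjusted p = 0.0706 to 0.0901 without Th0 control 173, 176 or 177 or Th0 Ezh2KO.165). Prdm1 rose from 4.98 ± 0.595 to 17.2 ± 4.93 CPM (log2 change 1.79, adjusted p = 0.0163, with adjusted p = 0.0566 to 0.0781 without Th0 control 173, 176 or 177 or Th0 Ezh2KO.165). Il4 (log2 change 2.47, adjusted p = 0.164), Gata3 (log2 change 0.52, adjusted p = 0.357) and Bcl6 (log2 change 0.26, adjusted p = 0.928) did not pass the threshold. Il17a had no reads in any library, which allows up to 3 counts in each. Il5 stayed below the count filter, with 40, 7 and 13 counts in libraries Ezh2KO.165, Ezh2KO.174 and Ezh2KO.175.

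**Figure D1:**
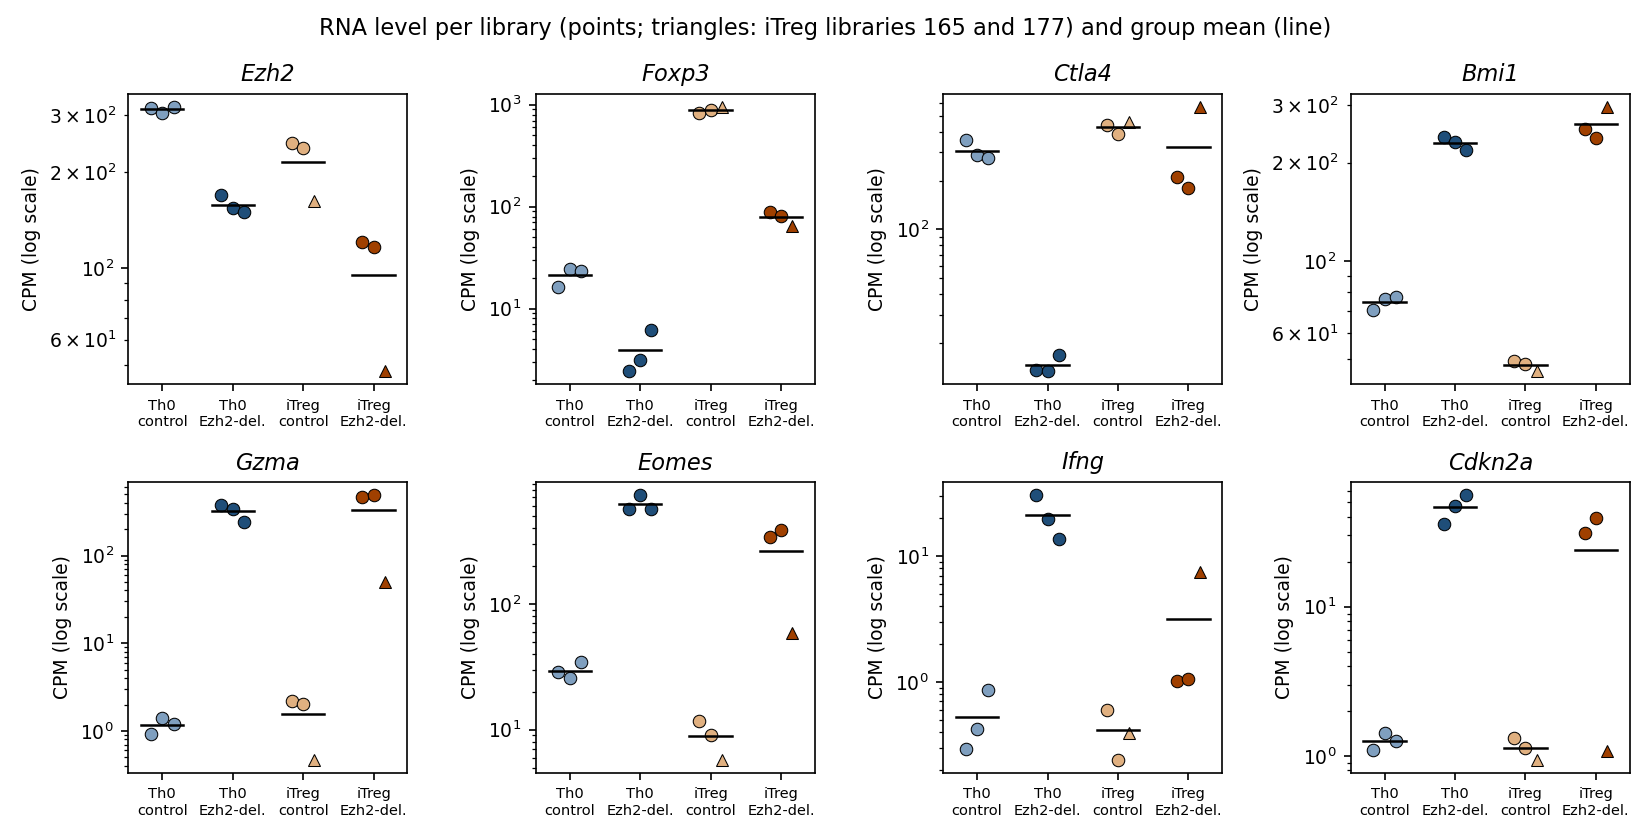
CPM (log scale) of 8 genes in each of the 12 RNA libraries by group, with a line at each group mean and triangles for the iTreg libraries Ezh2KO.165 and 177. Gzma lies near 1.18 CPM in control and 320.0 CPM in Ezh2-deleted Th0 cells, and Foxp3 near 896 CPM in control and 78.4 CPM in Ezh2-deleted iTreg cells.

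Across the Th0 transcriptome, 1536 of 12845 tested genes passed an adjusted p of 0.05, 1123 higher and 413 lower without Ezh2. This number depended on single libraries. It was 805, 799 and 839 without Th0 control 173, 176 and 177, 964, 981 and 1009 without Th0 Ezh2KO.165, Ezh2KO.174 and Ezh2KO.175, and 3529 without iTreg Ezh2KO.165. The excess of rises depended on the fit as well: 2056 were higher and 1473 lower without iTreg Ezh2KO.165, and 3258 and 3139 with the 6 Th0 libraries alone. Cytotoxic genes had the smallest list p: 10 of 14 rose over all genes and 13 adjusted over the list alone, among them Ctsw (log2 change 1.94). The list test gave adjusted p = 7.36e-14 (0.0346 with an estimated correlation). T helper 1 genes had 7 of 17 higher (7 adjusted over the list alone), including Ccl3, Ccl4 and Fasl at log2 changes of 4.23, 3.82 and 3.42 (adjusted p = 5.60e-05, or 0.0327 with an estimated correlation). These were the 2 list calls that held with an estimated correlation in Th0. T helper 2 genes, with Maf (2.58 to 47.1 ± 9.67 CPM) and Nfil3 (log2 change 2.53), had 5 of 14 higher and 10 adjusted over the list alone (adjusted p = 8.53e-05; 0.209 with an estimated correlation). Their mean log2 CPM was 4.18 in Ezh2KO.165 against 3.07 and 3.01 in Ezh2KO.174 and Ezh2KO.175, and 1.21 to 1.57 in the control libraries. B cell markers also stood higher in Ezh2KO.165, at 3.98 against 2.78 and 2.99. Without Th0 Ezh2KO.165 the T helper 2 median log2 change went from 2.77 to 2.21.

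The naive and memory, T cell identity and interferon response lists shifted down in Ezh2-deleted Th0 cells, list calls that were lost with an estimated correlation. The naive and memory list had a median log2 change of -0.96, with 1 of 13 lower (1 adjusted over the list alone; adjusted p = 0.00180, and 0.446 with an estimated correlation). In the T cell identity list Cd2 (650.1 ± 37.0 to 164 ± 18.7 CPM), Cd5 (log2 change -1.60) and Cd4 (-0.88) fell, 3 of 12 over all genes and 4 adjusted over the list alone (adjusted p = 0.000891; 0.247 with an estimated correlation). The interferon response list shifted down with 1 of 19 lower, Isg15, and 0 adjusted over the list alone (adjusted p = 0.0325; 0.526 with an estimated correlation). Control 173 carried part of the interferon shift. The list means were 5.36, 4.07 and 4.45 log2 CPM in control 173, 176 and 177 against 3.60, 4.19 and 4.35 in Ezh2KO.165, Ezh2KO.174 and Ezh2KO.175, and the median log2 change went from -0.49 to -0.26 without control 173. Isg15 lost its call without 1 library (adjusted p = 0.0620 to 0.117 without Th0 control 173 or Th0 Ezh2KO.165, Ezh2KO.174 or Ezh2KO.175). TGF-beta response genes rose in 5 of 13 (6 higher and 1 lower adjusted over the list alone), among them Id2 from 93.8 ± 4.72 to 722 ± 99.1 CPM (adjusted p = 0.0137; 0.281 with an estimated correlation). Of 39 Hox genes listed, 3 had enough counts to be tested. Hoxb4 and Hoxa4 rose (2 adjusted over the list alone, camera adjusted p = 0.00607, or 0.119 with an estimated correlation). Listed Hox genes outside these 3 stayed below the count filter, so a rise of the family was not shown. The p53 targets rose in 2 of 15 including Zmat3 (2 adjusted over the list alone; adjusted p = 0.0454; 0.391 with an estimated correlation). Marker lists of other cell types shifted up for B cells in 7 of 8 (7 adjusted over the list alone; adjusted p = 6.82e-06; 0.208 with an estimated correlation). The antigen presentation gene Cd74 had 52.5 CPM in control and 180.1 CPM in Ezh2-deleted cells. Markers of NK, NKT and gamma-delta T cells rose in 2 of 4 (4 adjusted over the list alone; adjusted p = 0.00430; 0.136 with an estimated correlation).

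The remaining Th0 lists did not pass the list test. Treg genes split, with 3 of 20 higher (Tigit by 2.27) and 8 lower, 5 and 8 adjusted over the list alone (adjusted p = 0.0780). Inhibitory receptors likewise had 5 higher and 2 lower of 9, with Havcr2 at a log2 change of 4.33 and Ctla4 lower (5 and 2 adjusted over the list alone; adjusted p = 0.0660). Tfh genes had 1 higher and 3 lower of 9 (2 and 3 adjusted over the list alone; adjusted p = 0.0817; their median and test were negative and their mean positive). Th17 genes had 2 higher of 5, Ahr (log2 change 3.88) and Rora (call lost at adjusted p = 0.0502 without Th0 control 176; 2 adjusted over the list alone; adjusted p = 0.0799). Cdk inhibitors had 3 higher and 1 lower of 7 (4 and 1 adjusted over the list alone; adjusted p = 0.105). Genes of PRC2 (adjusted p = 0.488), proliferation (0.440), glycolysis (0.583) and sex-linked genes (0.322) did not shift as lists, with no member called, over all genes or over the list alone. The same held for lists with a few called members, PRC1 (1 higher and 2 lower of 16; 0.775), apoptosis (1 higher of 20; 0.488), developmental transcription factors (2 higher of 6; 0.418), housekeeping (1 lower of 21; 0.266), myeloid (1 higher of 4; 0.290) and dendritic genes (1 higher of 3; 0.183), whose counts were the same adjusted over the list alone. Medians were negative and means positive for PRC1 and sex-linked genes, with a test direction of down. Sex was nevertheless not balanced between the genotypes. Xist had 27248 counts in Th0 Ezh2KO.165 and 25036 in iTreg Ezh2KO.165, against 2 to 21 in the other RNA libraries. The Y-linked Ddx3y had 10 and 4 counts there, against 2114 to 4635 in the other RNA libraries. Of 55 developmental transcription factors listed, 6 had enough counts to be tested. The same held for 5 of 12 Th17 genes, 3 of 6 dendritic and 4 of 13 myeloid markers. Of 8 markers of NK, NKT and gamma-delta T cells, 4 were tested. The CD8 T cell and erythroid lists had 2 tested members each and were not tested as lists, and 1 erythroid gene was lower adjusted over the list alone.

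Ezh2-deleted iTreg cells had less Foxp3, the gene that defines regulatory T cells, and more cytotoxic transcripts. Foxp3 fell from 896 ± 60.1 to 78.4 ± 12.9 CPM (log2 change -3.52, SE 0.327, adjusted p = 0.000133). The Treg surface protein Nrp1 (chromosome 8, 128359073 to 128505462) fell from 240.3 ± 84.7 to 22.0 ± 4.59 CPM (log2 change -3.45, adjusted p = 6.48e-05). Gzma rose from 1.56 ± 0.950 to 334 ± 246 CPM (log2 change 7.73, SE 0.939, adjusted p = 0.000516). Eomes rose from 8.84 ± 2.96 to 261 ± 176 CPM (log2 change 4.88, SE 0.630, adjusted p = 0.000706). Tbx21 rose from 4.36 ± 1.25 to 12.6 ± 4.96 CPM (log2 change 1.53, adjusted p = 0.00681). Il12rb2, the receptor chain for IL-12, rose from 14.6 ± 8.24 to 454 ± 272 CPM (log2 change 4.96, adjusted p = 0.000616). Car2 (chromosome 3, 14886426 to 14900769) went from 2.52 ± 1.44 to 233 ± 45.5 CPM and Plac8 (chromosome 5, 100553725 to 100572245) from 3.55 ± 1.96 to 258 ± 38.2 CPM, with log2 changes of 6.53 and 6.18 and adjusted p of 1.73e-05 and 1.73e-05. Asb2, Il10 and Ccl5 rose by 7.40, 6.17 and 5.85 (adjusted p = 0.000555, 0.00197 and 0.00701). Esm1 and Col9a2 were near 0 in control cells, at 0.0375 and 0.0396 CPM, against 6.34 ± 2.12 and 5.04 ± 7.24 CPM. The 8 largest falls were Dab2, Papln, Abcc8, Prok1, Cdhr3, Pyroxd2, Muc13 and Rassf4, with log2 changes of -6.52 to -5.44; Cdhr3 went from 42.9 ± 14.8 to 0.864 ± 0.482 CPM.

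Other fixed genes were less stable in iTreg. Ezh2 fell from 215 ± 46.0 to 95.1 ± 40.9 CPM (log2 change -1.18, SE 0.301, adjusted p = 0.0235, with adjusted p = 0.0781 to 0.0802 without iTreg control 154 or 155). Cdkn2a rose from 1.13 to 23.8 ± 20.1 CPM (log2 change 4.40, adjusted p = 0.0105), although library Ezh2KO.165 had 1.08 CPM. Bmi1 rose from 47.9 ± 1.79 to 263 ± 30.6 CPM (log2 change 2.45, adjusted p = 2.57e-06). Ifng reached 3.18 ± 3.71 CPM against 0.411 ± 0.180 CPM (log2 change 2.92, adjusted p = 0.0394). It lost its call in most fits without 1 library (adjusted p = 0.0505 to 0.140 without iTreg Ezh2KO.165, iTreg control 154, 155 or 177, Th0 control 173, 176 or 177 or Th0 Ezh2KO.165, Ezh2KO.174 or Ezh2KO.175). Gata3, the T helper 2 factor, fell from 86.4 ± 34.1 to 38.4 ± 6.64 CPM (log2 change -1.17, adjusted p = 0.0252, with adjusted p = 0.0687 to 0.0813 without iTreg Ezh2KO.150 or Ezh2KO.153 or iTreg control 177). Il4 rose by 4.69 (adjusted p = 0.0255, with adjusted p = 0.0528 to 0.0950 without iTreg Ezh2KO.150 or iTreg control 154, 155 or 177). Il13 (log2 change 2.81, adjusted p = 0.0954), Prdm1 (log2 change 0.90, adjusted p = 0.161) and Bcl6 (log2 change 0.50, adjusted p = 0.763) did not pass. Without iTreg Ezh2KO.165 the adjusted p was 0.0354 for Il13 and 0.00276 for Prdm1. Without it Bcl6 turned to a log2 change of -1.53 (adjusted p = 0.00232). Il13 also passed without Th0 Ezh2KO.165 (adjusted p = 0.0446).

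Over all genes, 2147 passed in iTreg, 1214 higher and 933 lower. The count was 5763 without iTreg Ezh2KO.165, where falls outnumbered rises (2733 higher and 3030 lower), and 1376 without iTreg control 155. T helper 1 genes gave the 1 list call that held with an estimated correlation in iTreg, with 13 of 17 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 7.08e-07, or 0.00986 with an estimated correlation). Fasl rose by 4.43, and the T helper 2 receptor Ccr4 fell from 154 ± 37.2 to 11.2 ± 6.20 CPM. Interferon response genes rose in 14 of 19 (16 adjusted over the list alone), with Usp18 from 2.02 ± 0.764 to 23.2 ± 5.34 CPM, Mx1 from 0.638 ± 0.488 to 9.95 ± 0.658 CPM and Gbp2 from 246 ± 76.0 to 641 ± 100.2 CPM (adjusted p = 7.10e-11; 0.204 with an estimated correlation). Cytotoxic genes had 11 of 14 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 9.88e-07; 0.180 with an estimated correlation). Their mean log2 CPM was 4.62, 4.54 and 2.63 in Ezh2KO.150, Ezh2KO.153 and Ezh2KO.165, against 1.53, 1.47 and 0.602 in control 154, 155 and 177. NK, NKT and gamma-delta T cell markers varied alike (0.146, 0.152 and -1.77 in the same Ezh2-deleted libraries) and did not pass as a list, with 1 of 4 higher (1 adjusted over the list alone; median log2 change 1.96, adjusted p = 0.221). Treg genes had 9 of 20 lower and 2 higher (11 and 2 adjusted over the list alone), with Foxp3 and Nrp1 lower and Tigit higher by 4.62 (list adjusted p = 0.00487; 0.0894 with an estimated correlation). The p53 targets rose in 3 of 15 (6 adjusted over the list alone; adjusted p = 0.00733; 0.357 with an estimated correlation), among them Zmat3 and Ccng1. B cell markers went the other way than in Th0, 5 of 8 lower (6 adjusted over the list alone; adjusted p = 0.000459; 0.357 with an estimated correlation). Dendritic markers rose in 3 of 3, Zbtb46, Xcr1 and Flt3 (Xcr1 with adjusted p = 0.0579 to 0.110 without iTreg Ezh2KO.150 or Ezh2KO.153 or iTreg control 154, 155 or 177; Flt3 with adjusted p = 0.0594 to 0.164 without iTreg Ezh2KO.150 or Ezh2KO.153, iTreg control 154 or 155, Th0 control 173, 176 or 177 or Th0 Ezh2KO.165, Ezh2KO.174 or Ezh2KO.175; 3 adjusted over the list alone; adjusted p = 0.00731; 0.114 with an estimated correlation). Of 6 dendritic markers listed, only these 3 had enough counts to be tested. Their mean log2 CPM was low, at 1.01, 0.872 and 0.177 in Ezh2KO.150, Ezh2KO.153 and Ezh2KO.165. In control 154, 155 and 177 it was -1.50, -1.55 and -1.41. Of the other lists, T helper 2 genes split into 2 higher and 4 lower of 14 (3 and 5 adjusted over the list alone; adjusted p = 0.359). Inhibitory receptors split into 5 higher and 1 lower of 9 (6 and 2 adjusted over the list alone; adjusted p = 0.107). Naive and memory (adjusted p = 0.261), TGF-beta response (0.490), Hox (0.532), proliferation (0.111) and glycolysis genes (0.638) did not shift as lists. Their medians, means or tests differed in sign for T helper 2 genes (median and test negative, mean positive) and Hox genes (mean negative, median and test positive).

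**Figure D2:**
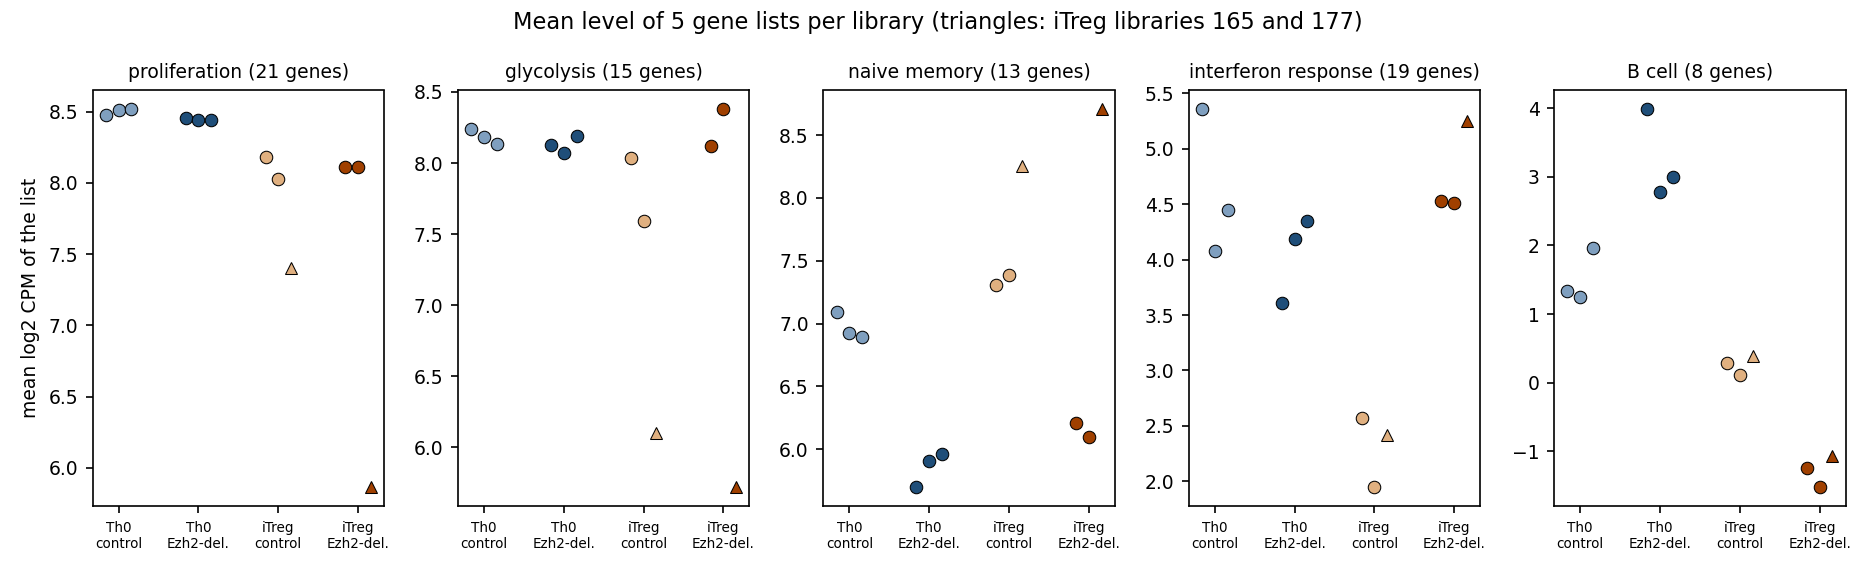
Mean log2 CPM of 5 gene lists in each of the 12 RNA libraries by group, with triangles for the iTreg libraries Ezh2KO.165 and 177. Interferon response genes (19 members) lie higher in Ezh2-deleted than in control iTreg libraries at a median log2 change of 2.28, and B cell genes (8 members) are highest in Ezh2-deleted Th0 libraries.

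The 2 cultures shared much of the response. Of 12845 genes, 557 were higher without Ezh2 in both Th0 and iTreg against 106 expected (odds ratio 16.6, one-sided Fisher exact p = 4.88e-310). Another 205 were lower in both against 30.0 expected (odds ratio 15.8, one-sided Fisher exact p = 1.78e-126). The expected numbers and p-values take genes as independent replicates, which they are not. Both contrasts also came from 1 fit that shares the spread of each gene, and the numbers of Ezh2KO.165 and 177 occur in both cultures. The p-values therefore describe the overlap of the 2 gene sets and do not measure how well it would repeat in other animals. Gzma, Eomes, Il10, Cdkn2a and Bmi1 were among the shared rises, and Foxp3 and Cdhr3 among the shared falls. The shared rises numbered 339, 320 and 327 without Th0 control 173, 176 and 177, and 1086 without iTreg Ezh2KO.165. Averaged over both cultures, 2690 genes passed, 1679 higher and 1011 lower, and 5775 without iTreg Ezh2KO.165, 2899 higher and 2876 lower. On the average, T helper 1 genes again rose (12 higher and 1 lower of 17; 13 and 1 adjusted over the list alone; adjusted p = 5.39e-07, or 0.00930 with an estimated correlation).

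Other genes answered the deletion differently in Th0 and iTreg. The interaction of genotype and culture passed for 577 genes, 209 with a higher and 368 with a lower change in iTreg. Its count was 271, 291 and 306 without Th0 control 173, 176 and 177, 320, 292 and 317 without Th0 Ezh2KO.165, Ezh2KO.174 and Ezh2KO.175, 370 and 2552 without iTreg Ezh2KO.150 and Ezh2KO.165, and 304 without iTreg control 155. Interferon response genes rose more in iTreg in 11 of 19 (17 adjusted over the list alone; adjusted p = 5.57e-20; 0.101 with an estimated correlation). B cell genes (0 higher and 7 lower of 8, 7 adjusted over the list alone; adjusted p = 2.08e-13; 0.101 with an estimated correlation) and T helper 2 genes (5 lower of 14, 8 adjusted over the list alone; adjusted p = 2.39e-06; 0.207 with an estimated correlation) rose more in Th0 or fell more in iTreg. Smaller shifts covered the TGF-beta response (1 lower of 13, 3 adjusted over the list alone; adjusted p = 0.000805; 0.288 with an estimated correlation), T cell identity (1 higher of 12, 3 adjusted over the list alone; 0.000899; 0.327 with an estimated correlation) and Th17 lists (1 lower of 5, 2 adjusted over the list alone; 0.00625; 0.101 with an estimated correlation). None of the fixed genes with enough counts to be tested passed for the interaction, so a difference between cultures was not shown for Foxp3 (interaction log2 -1.07, adjusted p = 0.247), Ifng (-2.40, 0.382) or Tbx21 (1.21, 0.164).

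Control cells showed how iTreg and Th0 libraries differed with Ezh2 present. Foxp3 rose from 21.5 ± 4.53 CPM in Th0 to 896 ± 60.1 CPM in iTreg (log2 change 5.38, adjusted p = 2.29e-05), along with the Treg genes Nrp1 (log2 change 4.68, adjusted p = 1.82e-05), Nt5e (log2 change 3.61, adjusted p = 5.46e-05) and Ikzf4 (log2 change 2.22, adjusted p = 0.000170). Feedback regulators of TGF-beta signalling rose too: Pmepa1 from 21.9 ± 2.65 to 144 ± 35.6 CPM, Skil from 45.6 ± 3.98 to 441 ± 195 CPM, and Ldlrad4 by 6.74. Tbx21 fell from 28.7 ± 2.58 to 4.36 ± 1.25 CPM (log2 change -2.72, adjusted p = 0.000375). Eomes fell (log2 change -1.74, adjusted p = 0.0391), while Gata3 rose by 1.09 (adjusted p = 0.0233) and Bcl6 by 2.76 (adjusted p = 0.0325). These 3 calls were lost without single libraries: for Eomes adjusted p = 0.0565 to 0.130 without iTreg control 154, 155 or 177, Th0 control 173, 176 or 177 or Th0 Ezh2KO.165, Ezh2KO.174 or Ezh2KO.175; for Gata3 adjusted p = 0.0590 to 0.0836 without iTreg control 177 or Th0 control 173, 176 or 177; for Bcl6 adjusted p = 0.0531 to 0.107 without iTreg control 154, 155 or 177 or Th0 control 173, 176 or 177. The largest rises were Abcc8, from no reads to 40.8 ± 35.7 CPM, Plekhd1, from 0.106 to 42.6 ± 28.4 CPM, and Adamtsl2, Hepacam2, Kirrel, Ceacam15, Peli2 and Klri2, each under 1 CPM in Th0. The largest falls were the interferon-induced Ifi44, Mx1, Isg15 and Ifit1, with Gucy1a3, Tbkbp1, Tg and Ms4a4c, at log2 changes of -6.07 to -3.80. Ezh2 itself did not pass (log2 change -0.54, adjusted p = 0.171).

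That culture comparison called 4027 genes, 2555 higher and 1472 lower in iTreg, and 3238 and 3262 with its 6 libraries alone. It called 2201, 2004 and 2256 without Th0 control 173, 176 and 177. It called 2518 without iTreg control 177, and 8195 without iTreg Ezh2KO.165, which the comparison uses only for its estimate of spread. TGF-beta response genes rose in 10 of 13 with 1 lower (10 and 1 adjusted over the list alone; adjusted p = 7.36e-05; 0.279 with an estimated correlation). Treg genes rose in 7 of 20 (7 adjusted over the list alone; adjusted p = 0.00970; 0.221 with an estimated correlation). Interferon response genes fell in 14 of 19 (15 adjusted over the list alone; adjusted p = 5.53e-07; 0.482 with an estimated correlation). Proliferation and glycolysis lists shifted down by medians of -0.63 and -0.90 without a member passing on its own (both adjusted p = 0.0320; 0.787 with an estimated correlation). Housekeeping genes shifted down too (4 of 21 lower, 4 adjusted over the list alone; adjusted p = 0.00970; 0.787 with an estimated correlation). So did T helper 1 genes (1 higher and 5 lower of 17, 1 and 5 adjusted over the list alone; adjusted p = 0.0263; 0.238 with an estimated correlation) and B cell genes (3 of 8 lower, 3 adjusted over the list alone; adjusted p = 0.0123; 0.779 with an estimated correlation). Mean log2 CPM of the glycolysis list was 8.04, 7.59 and 6.10 in iTreg control 154, 155 and 177, against 8.13 to 8.24 in Th0 control libraries, and of the proliferation list 8.18, 8.03 and 7.41 against 8.48 to 8.52. With iTreg Ezh2KO.165 and 177 left out, a test chosen after seeing the data, the adjusted p was 0.210 for glycolysis (median -0.52) and 6.14e-05 for proliferation (median -0.45). With a term for these 2 libraries it was 0.215 and 0.486. In Ezh2-deleted cells the same comparison called 3262 genes, 2138 higher and 1124 lower, which became 3732 and 3749 with iTreg Ezh2KO.165 and 177 left out. It called 1135, 1121 and 1110 without Th0 Ezh2KO.165, Ezh2KO.174 and Ezh2KO.175. Treg genes still rose there in 7 of 20 (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.0223; 0.271 with an estimated correlation), with Foxp3 at 3.94 CPM in Th0 and 78.4 CPM in iTreg. TGF-beta, the IL-2 dose, the day given in the titles and most of the library numbers differed together between the cultures and cannot be told apart.

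H3K27me3 in Th0 cells showed where the mark depended on Ezh2. Its density over developmental genes, the classic Polycomb targets, collapsed without the enzyme: Hox genes went from a median of 7.24 to 1.46 CPM per kb with 31 of 31 lower. Developmental transcription factors went from 6.35 to 1.43 with 53 of 53 lower. The list adjusted p were 2.79e-33 and 6.51e-43, and 0.424 for both with an estimated correlation. Both families stayed lower under the other scalings, with 31 of 31 and 51 of 53 called when libraries were scaled on highly expressed genes. In RNA, 3 of 39 listed Hox genes and 6 of 55 listed developmental transcription factors had enough counts to be tested. The largest losses were at Hes5 (chromosome 4, 154960923 to 154962371; 7.00 to 0.560 CPM per kb, log2 change -3.60, adjusted p = 0.000424), Id1, Oxt, Wnt1 and Ascl5, at log2 changes of -3.60 to -2.77. Cdkn2a lost the mark from 6.27 to 1.60 CPM per kb (log2 change -1.97, adjusted p = 5.46e-05), Eomes from 4.12 to 0.947 (log2 change -2.12, adjusted p = 0.000407) and Il10 had a log2 change of -1.12 (adjusted p = 0.00480). Prdm1, Il4, Cyp1b1, Gcnt2, Nrn1, Il17a, Gzma and Ccr2 also had less mark, at log2 changes of -1.97 (Cyp1b1) to -0.65 (Ccr2). By library size Ifng did not pass (0.791 and 0.784 CPM per kb, edgeR adjusted p = 0.977), nor did Il5, Il13, Gata3, Bcl6 or Xcl1 pass. With the scaling on highly expressed genes, 7 named genes with a negative but uncalled change by library size passed with less mark. Most of Ifng, Il5, Il13 and Xcl1 were among them. Stxbp6 (log2 change -0.60, edgeR adjusted p = 0.0255) and Trat1 (-0.65, edgeR adjusted p = 0.0179) also passed as lower there, from a positive change by library size. As lists, cytotoxic (5 of 15 lower, 1 higher; adjusted p = 0.0917), Th17 (5 of 12 lower, 1 higher; 0.0556), T helper 2 (5 of 18 lower, 2 higher; 0.123), T helper 1 (3 of 17 lower, 4 higher; 0.914) and Treg genes (2 of 20 lower, 7 higher; 0.860) did not pass. The T helper 1 median of 0.10 was positive while its test direction was down. These counts are for library size scaling. With the scaling on highly expressed genes, 11 of 15 cytotoxic, 10 of 12 Th17 and 7 of 17 T helper 1 genes were lower and 0 higher. With that scaling 12 of 18 T helper 2 and 12 of 20 Treg genes were lower, and 1 of each was higher. The direction for Treg genes therefore depended on the scaling. Intervals of Foxp3 and Esm1 gave no value. Both are wholly covered by other intervals, and all 1254 intervals of this kind held no reads, against 9 of 17394 without overlap.

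Across all intervals the mark evened out in Ezh2-deleted cells. With library size as the scaling, 10775 of 20376 intervals passed, 6570 higher and 4205 lower, around a median log2 change of 0.21 for all intervals. TMM scaling moved this median to -0.02, and scaling on highly expressed genes to -0.58, which left 3.91% of 9260 calls higher. Rises are therefore relative to the library total. Housekeeping genes rose in 16 of 20 intervals from a median of 0.377 to 0.859 CPM per kb (13 with TMM and 1 with the scaling on highly expressed genes; list adjusted p = 3.77e-04; 0.424 with an estimated correlation). T cell identity genes rose in 9 of 12, PRC2 genes in 10 of 11 and naive and memory genes in 8 of 12 (list adjusted p = 0.00307, 0.00443 and 0.0147; 0.424 for each with an estimated correlation). With the scaling on highly expressed genes no member of these lists rose, while 1 T cell identity gene and 1 naive and memory gene fell. Tbx21 rose by 1.01 (adjusted p = 0.00673) and Ezh2 by 0.91, calls lost with that scaling. Ctla4 rose by 0.55 (adjusted p = 0.0477) but turned to -0.22 with it. The 5 largest rises, at Mgat2, Psme2, Hspe1, Cox20 and Tmem81, had log2 changes of 2.29 to 2.95. Intervals above 2 times the even density of 0.995 CPM per kb numbered 2356 and 2764 in the control libraries and 139 and 350 in the Ezh2-deleted libraries. Without either Ezh2-deleted library, Ezh2KO.10 or Ezh2KO.9, edgeR called 0 intervals, with 7223 and 7401 at an unadjusted p under 0.05, and every gene named here lost its call. Without control 33 or 7 it called 12648 and 10641, and DESeq2 called 11218 with all 4 libraries. Each fit without 1 library leaves a genotype with 1, which is assumed to vary like the other genotype. In the simulated data the false share of H3K27me3 calls was above the threshold. Calls close to it, such as those of Ctla4 and Gzma, are therefore less certain than their adjusted p states.

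**Figure D3:**
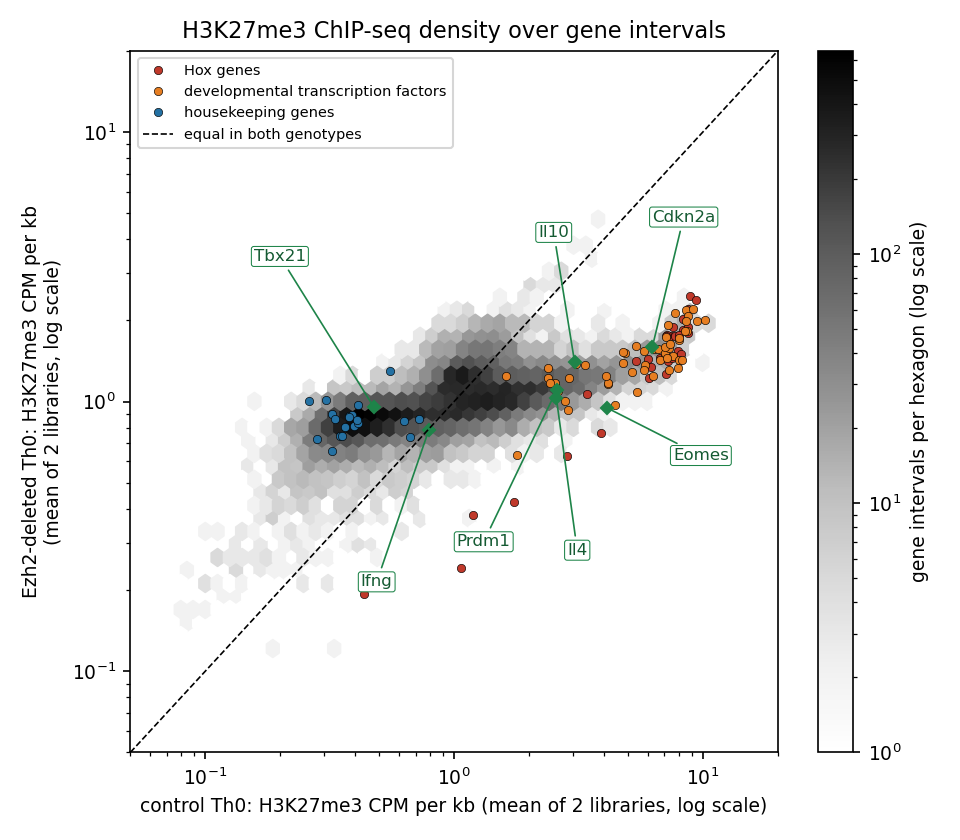
H3K27me3 density (CPM per kb, log axes) of gene intervals in control against Ezh2-deleted Th0 cells, means of 2 libraries each, with Hox genes in red, developmental transcription factors in orange, housekeeping genes in blue and a dashed line of equality. Hox genes fall from a median of 7.24 to 1.46, and housekeeping genes rise from 0.377 to 0.859 with library size scaling, a rise called in 16 of 20 that is kept in 1 with the scaling on highly expressed genes.

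Among genes with enough RNA counts to be tested, those with the most H3K27me3 in control Th0 cells tended to rise without Ezh2. Marked genes silent in all groups were left out by the count filter. A gene silent in control cells enters only if another group expresses it, which by itself favours a rise. The marked genes were the 1259 of 12592 with the highest control density, at or above 1.47 CPM per kb. Their RNA changed by a median log2 of 0.95 (1.94-fold) in Th0, and 375 rose and 19 fell. A log2 change above 0 was seen in 77.7% of them. The median was 0.50 with the strict filter, 0.36 with density not divided by length and 0.63 with the top 20% as marked genes. Eomes, Cdkn2a, Il10, Cyp1b1 and Gcnt2 lost the mark and rose together. That was 29.8% of marked genes higher against 6.49% of the others (odds ratio 6.11, 95% interval 5.28 to 7.05, two-sided Fisher exact p = 3.86e-118). The set test gave p = 2.64e-21 (1.07e-05 with an estimated correlation). In 24 marked genes a group had no reads, and with these at their bound, 3 counts, the median was 0.94. None of 10000 random lists matched on mean expression reached it, the highest median being 0.25. In iTreg cells, whose H3K27me3 was not analysed here, the same genes had a median of 0.44 (0.43 with 9 genes at their bound), and 298 rose and 125 fell (set p = 7.72e-05; 0.00191 with an estimated correlation). That median was 0.23 with the strict filter, 0.19 with density not divided by length and 0.29 without iTreg Ezh2KO.165. Of marked genes 23.7% were higher against 7.93% of the others (odds ratio 3.60, 95% interval 3.10 to 4.18, two-sided Fisher exact p = 1.37e-56). Marked genes were also lower more often than others in iTreg, 9.93% against 6.99% (odds ratio 1.47, two-sided Fisher exact p = 2.46e-04). Across the 12592 genes, which are not independent replicates, Spearman's rho of control density and RNA change was 0.27 in Th0 and 0.17 in iTreg.

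**Figure D4:**
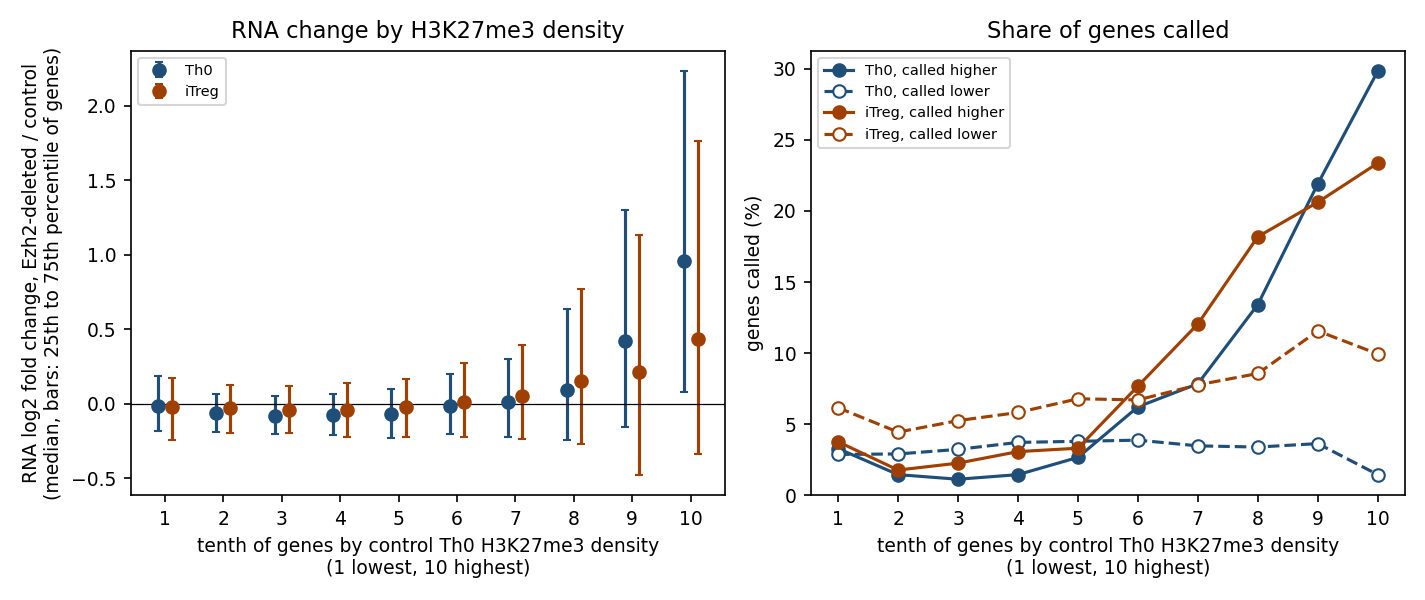
RNA log2 change without Ezh2 (median, with bars from the 25th to the 75th percentile) and the percent of genes called higher or lower, in 10 groups of genes by control H3K27me3 density, for Th0 and iTreg. In the group with the most mark 29.8% of genes were higher and 1.46% lower in Th0, and 23.4% higher and 9.94% lower in iTreg.

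The mark itself fell at most marked genes. Of 1254 with a ChIP test, 1124 had less H3K27me3 and 8 more with library size scaling, 1195 and 3 with TMM, and 1224 and 0 with the scaling on highly expressed genes. The median density went from 2.05 to 1.07 CPM per kb. The set was chosen on the control libraries of that test, which by itself favours a fall. In a test chosen after seeing the data, the 1259 genes with the most mark in control 33 had a median of 2.15 in control 7 and 1.07 in Ezh2-deleted cells (1229 lower), and those chosen in control 7 had 1.95 in control 33 and 1.07 (1179 lower). Among genes higher in Ezh2-deleted Th0 cells, 434 of 1072 had less mark, 40.5% against 8.84% of genes not called. Against all other genes, called lower or not called, the odds ratio was 7.10 (95% interval 6.16 to 8.17, two-sided Fisher exact p = 1.75e-148, 11968 genes tested in both). The 434 became 566 with TMM and 773 with the scaling on highly expressed genes. Density was nearly even in Ezh2-deleted cells, with 25th and 75th percentiles of 0.873 and 1.13 CPM per kb in Ezh2KO.10. In Ezh2KO.9 they were 0.803 and 1.14. The called change of the mark therefore largely follows control density, and this odds ratio is not separate from the result for marked genes. Gzma, with the largest rise, had a smaller loss of mark, from 1.72 to 1.07 CPM per kb (log2 change -0.68, adjusted p = 0.0352). By library size Ifng rose with no called change of the mark, and 158 genes rose with more mark. Of 387 genes lower in RNA, 24 had less mark and 211 more by library size, 54.5% with more against 56.7% of genes not called, so the genes that fell did not stand out by a gain. The scaling on highly expressed genes called 362 intervals higher among all tested. Among the 8 largest falls in RNA, Nrn1 had less mark, from 2.91 to 1.22 CPM per kb (log2 change -1.25, adjusted p = 0.00221, with adjusted p = 0.102 to 0.113 without Th0 Ezh2KO.10 or Ezh2KO.9). Ctla4 had more with library size scaling, a call lost with TMM and with the scaling on highly expressed genes, which turned it to -0.22. Abi3bp, Dapl1, Cdhr3, Igfbp7, Stxbp6 and Trat1 did not pass with library size scaling, at log2 changes of -0.35 to 0.19, and all 6 passed as lower with the scaling on highly expressed genes, at -1.14 (Cdhr3) to -0.60 (Stxbp6).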

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

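The tests of sex, of a separate culture batch, of B cells, of CD8 T cells and of the mark at Cd8a were chosen only after the result was seen; the tests of library size, of the mark at B cell genes and of other splits were planned.

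The interaction test marked out 5 genes whose response to the deletion differed most clearly between cultures. Sgk1 rose in Th0 (15.1 to 56.4 CPM, log2 change 1.90) and fell in iTreg (166 to 31.6 CPM, -2.39), an interaction log2 of -4.30 (edgeR adjusted p = 0.000343). Fes (1.24 in Th0, -3.43 in iTreg), Zcchc24 (2.24, -0.67) and Gna15 (1.54, -1.08) moved the same way, with interaction log2 of -4.67, -2.91 and -2.61 (edgeR adjusted p = 0.000351, 0.000421 and 0.000421). Gimap7 moved the other way (-0.86 in Th0, 3.95 in iTreg), an interaction log2 of 4.81 (edgeR adjusted p = 0.000351). These 5 interaction calls held with each of the 12 libraries left out in turn. TGF-beta, the IL-2 dose, the day given in the titles and most of the library numbers differed together, so which of them lies behind these differences was not tested.

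Other splits of the same libraries were counted for each model. In Th0, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 1536 genes, and the highest other gave 0. The same held for the marked genes in Th0 (1 of 10; median 0.95, highest other 0.37) and for genes higher in RNA with less mark (1 of 10; 434, highest other 0). It held for the marked genes in iTreg (1 of 10; 0.44, highest other 0.19), the control culture comparison (1 of 10; 4027, highest other 0) and that in Ezh2-deleted cells (1 of 10; 3262, highest other 0). In iTreg 2 of the 10 splits gave as many as 2147 genes, and the highest other gave 2905. That split set Ezh2KO.150, Ezh2KO.153 and 154 against 155, Ezh2KO.165 and 177. The other 3 splits that put Ezh2KO.165 and 177 together gave 0 in edgeR. These splits mix the genotypes and hold the genotype effect in the spread, so they cannot tell whether this pairing accounts for the count. With a term for these 2 libraries the genotype called 4991 genes. In all of these, 10 splits are too few for a share under 0.05.

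For results over both cultures, 60 of the 200 joint splits were drawn with a fixed seed. The average was reached by 1 of 60 (2690 genes, highest other 1285) and genes higher in both cultures by 1 of 60 (557, highest other 0). These 2 shares lie under 0.05, which argues against a chance division of the libraries into genotypes. Other splits hold the genotype effect in the spread, which lowers their counts, so the shares do not measure the size of either result. For the shared rises they do not test the sharing apart from the genotype effect. A difference in sex or animals that goes with the genotype is not excluded. The interaction was reached by 2 of 60 (577, highest other 1285, more than the real grouping gave). Because splits of the genotype labels move the genotype effect into the spread, they do not test the interaction by itself, and chance stays open for it.

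The iTreg libraries Ezh2KO.165 and 177 stood apart from the other 4 iTreg libraries, with 8576 genes called for the set, 4214 higher and 4362 lower. Library size is argued against, since 8521 genes were called after all libraries were thinned to the lowest total. Sex is argued against as the whole cause, because 177 carried Y-linked transcripts and Ezh2KO.165 did not, yet their deviations from the other libraries had a Pearson r of 0.737 across genes. A separate culture or library batch of cells that divided less may lie behind it and stays open: the proliferation list deviated by a median log2 of -0.68 in 177 and -2.09 in Ezh2KO.165, but a batch cannot be told apart from these animals. The deviations of the Th0 and iTreg libraries of the same number had a Pearson r of 0.0445 for Ezh2KO.165 and -0.00307 for 177, so the Th0 libraries did not share the pattern. A difference between the animals that shows in iTreg culture alone stays open, and whether a number is 1 animal in both cultures was not known.

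B cell genes were higher in Ezh2-deleted Th0 cells (7 of 8, median log2 change 1.79). More B cells in the Ezh2-deleted cultures are a candidate explanation: the genes varied together, with an SD of 0.211 around a median log2 ratio of 1.07 for Ezh2KO.165 over Ezh2KO.174 and Ezh2KO.175. Antigen presentation genes had a median log2 change of 1.93 in Th0 (the abundant Cd74 from 52.5 to 180.1 CPM). They did not follow B cell genes in iTreg, where their median was 1.66, with H2-Aa and H2-Ab1 higher (edgeR adjusted p = 0.00122 and 0.0109), so their rise does not single out B cells. The flow sort of naive CD4 T cells would also remove B cells. Of the 8 genes, 6 had at least 1 CPM in control Th0 cells and 0 were in another list, and in iTreg the median of the 8 was -2.22. The T helper 2 list also stood higher in Ezh2KO.165, with a median log2 ratio of 0.96. Ezh2KO.165 was the only Th0 library with high Xist counts (27248), so sex cannot be told apart from other differences of this library. Loss of H3K27me3 at these genes in the T cells themselves could also raise them and stays open, as the mark was lower at 3 of 7 and higher at 0 in edgeR with all 4 libraries, a test that calls 0 intervals without Ezh2KO.10 or Ezh2KO.9.

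Cd8a was higher in the iTreg libraries Ezh2KO.150 and Ezh2KO.153, at 119.5 and 115.3 CPM, than in Ezh2KO.165 (17.4 CPM) and in control iTreg cells (mean 13.6 CPM). CD8 T cells in these cultures are argued against, since they would raise Cd8b1 alike: over the 4 libraries Ezh2KO.150, Ezh2KO.153, 154 and 155 the log2 change was 2.85 for Cd8a and 0.68 for Cd8b1, a difference of 2.18 (SE 0.443). Loss of H3K27me3 at Cd8a may contribute and stays open. The mark there had a log2 change of -0.62 in Th0 (edgeR adjusted p = 0.0798) and lay at the 73.6th percentile of control density, and H3K27me3 in iTreg was not analysed here.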

How the results depend on the processing

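Genes called in the report mostly kept their direction, while the number called and the balance of rises and falls shifted. The term for the iTreg libraries Ezh2KO.165 and 177, leaving these 2 out, leaving out Ezh2KO.165 in both cultures, leaving out overlapping intervals and choosing marked genes in 1 control library to measure their mark against the other were tests chosen only after the result was seen; the other alternatives were planned. The cause of each shift below was not tested.

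In Th0, 1536 genes passed. There were 982 with the strict filter, 2359 with the DESeq2 Wald test and 6397 with the 6 Th0 libraries alone. Of the 1536, 1123 were higher and 413 lower, against 3258 and 3139 with the 6 libraries alone. Adding the term for the iTreg libraries gave 4112 (2336 higher, 1776 lower), leaving these 2 out 6697 (3415 higher, 3282 lower), and leaving out Ezh2KO.165 in both cultures 2555. Leaving out 1 library gave 799 to 3529. All 1536 genes kept their direction and call with the term and with the 2 libraries left out, and 1529 with DESeq2. DESeq2 size factors, no filter, the random effect (estimated correlation -0.009) and the sex covariate gave 1537, 1392, 1441 and 1770.

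In iTreg, 2147 genes passed. There were 539 with the 6 iTreg libraries alone, 4991 with the term (2440 higher and 2551 lower, against 1214 and 933), 7409 with the 2 libraries left out and 5391 without Ezh2KO.165 in either culture, and 1376 to 5763 with 1 library left out. The term kept all 2147 calls in their direction, leaving the 2 libraries out kept 2120, and DESeq2 kept 2138. The average over cultures (2690 genes) gave 5662, 7892 and 5042 with these 3 alternatives in turn, and 2100 to 5775 with 1 library left out. The interaction (577 genes) gave 2366, 5347 and 1805, besides 1266 with DESeq2 and 271 to 2552 with 1 library left out.

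The control culture comparison (4027 genes) gave 6500 with its 6 libraries alone (3238 higher and 3262 lower, against 2555 and 1472), 6499 with the term, 8673 with the 2 libraries left out, 7989 without Ezh2KO.165 and 2004 to 8195 with 1 library left out. In Ezh2-deleted cells (3262 genes) these were 596, 5965 (3114 higher and 2851 lower) and 7481 (3732 and 3749, against 2138 and 1124), with 2501 without Ezh2KO.165 and 1110 to 4316 with 1 library left out. Genes higher in both cultures (557) numbered 365 with the strict filter, 1891 with the 2 libraries left out, 940 without Ezh2KO.165 and 320 to 1086 with 1 library left out.

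For H3K27me3 (10775 intervals) leaving out 1 library gave 0 to 12648 in edgeR, with a lone library assumed to vary like the other genotype. The other settings gave 8624 to 11218. Without Ezh2KO.10 or Ezh2KO.9, 7223 and 7401 intervals had an unadjusted p under 0.05. Genes with less mark among those higher in Th0 (434) numbered 566 with TMM, 773 with scaling on highly expressed genes and 799 with the 2 iTreg libraries left out.

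The median RNA change of marked genes kept its direction under every alternative run: 0.36 to 1.08 in Th0 (0.95 in the report; 0.92 to 1.06 with 1 library left out) and 0.19 to 0.58 in iTreg (0.44 in the report; 0.29 to 0.58 with 1 library left out). The lowest values came with density not divided by length, and the strict filter gave 0.50 in Th0 and 0.23 in iTreg. List tests were less stable. With an estimated correlation between genes, camera lists passing an adjusted p of 0.05 went from 11 to 2 in Th0, from 7 to 1 in iTreg, from 8 to 0 in the control culture comparison and from 6 to 0 for the interaction.

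Across named genes, 5152 combinations of gene and alternative kept the direction and the call, 458 lost a call, 42 gained 1 and 27 reversed. In RNA, Bcl6 reversed in Th0 with the sex covariate (log2 change -0.34). In iTreg it reversed with the random effect (-0.43), the sex covariate (-1.01), the term (-0.35), the 2 libraries left out (-1.33), without iTreg Ezh2KO.165 (-1.53; -1.53 to 0.98 with 1 library left out) and without that number in both cultures (-1.53). In the control culture comparison Ifng turned to 0.20 without Th0 control 177 (-0.72 to 0.20 with 1 library left out) and Cdkn2a to 0.56 with the term.

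The other reversals were in H3K27me3. Scaling on highly expressed genes turned Gata3 to -0.50, Bcl6 to -0.39, Igj to -0.47, Ctla4 to -0.22, Stxbp6 to -0.60 (adjusted p = 0.0255), Trat1 to -0.65 (adjusted p = 0.0179) and the Ifng-22 interval to -0.63. TMM turned Stxbp6 to -0.0453, Trat1 to -0.10 and Ifng-22 to -0.0874. With 1 library left out, Ifng ranged from -0.37 to 0.42, with 0.42 without control 33 and 0.14 without Ezh2KO.10. Il13 ranged from -0.80 to 0.11, the latter without Ezh2KO.9. Ifng-22 ranged from -0.0698 (without control 33) to 0.42, with -0.0640 without Ezh2KO.9. Igj ranged from -0.0803 (without control 7) to 0.76. Dapl1 ranged from -0.28 to 0.0133 and Igfbp7 from -0.36 to 0.0823, in both cases reversed without control 33.

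Depth limits the short and weakly expressed genes. The Ifng-22 interval held 7 to 11 ChIP counts per library, Il5 stayed below the count filter and Il17a had no reads in RNA, so small changes there would be missed.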

Other observations

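The test below of mark loss against RNA was planned; no test in this part was chosen only after the result was seen.

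Genes that lost more of the mark may have risen more, which is a hypothesis from these data. Across 1254 marked genes, which are not independent replicates, Spearman's rho between the H3K27me3 change and the RNA change in Th0 was -0.136 (permutation p = 1e-05, the smallest that 100000 resamples can give), and -0.135 with the ranks of control density removed. The marked genes with the largest losses (median mark log2 change -1.65 over the first of 4 equal groups) had a median RNA log2 change of 1.11, against 0.54 in the group with the smallest losses (median mark log2 change -0.58). The association is weak, and ChIP and RNA came from different libraries, so it speaks for groups of genes and not for a single gene.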
